A study of Mus musculus with 4 samples.

How the data were processed

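Gene expression was measured in crypt epithelium of the mouse jejunum, the middle part of the small intestine. Crypts are the pits of the intestinal lining that hold the stem cells and their dividing progeny. Per the labels, crypts were freed with EDTA and passed through a 70 um filter, RNA was isolated with Trizol, and biotin-labelled total RNA was hybridised to Affymetrix arrays by the manufacturer's procedure. The knockout mice carried floxed Yy1 alleles and Vil-Cre-ERT2, a Cre recombinase fused to a tamoxifen-sensitive estrogen receptor domain and driven by the Villin promoter of the intestinal epithelium. Tamoxifen was given for 4 days. All 4 arrays carry the same treatment label, which was read as tamoxifen in both groups, although its wording leaves open whether the control mice received it. The labels name the other group only as control, and its genotype was not given in the sources used here. Groups and replicate numbers came from the sample titles, which call the replicates biological, with 2 arrays per group.

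The values are linear intensity values, 1 per probe set and array, as deposited by the authors. A probe set is a group of short oligonucleotides on the array that report on the same transcript. The summary method, background correction and normalization behind these intensities were not given in the sources used here. The lowest value was exactly 1, a floor reached by 16 to 27 probe sets per array. Median intensities were 139, 143, 141 and 141 in control replicates 1 and 2 and knockout replicates 1 and 2, so no further scaling was applied in the reported fit. Detection calls were not used here. As a measure of background, the median over 27 control probe sets for Bacillus genes lay between 31.9 and 35.6 in the 4 arrays. These were taken because their bacterial transcripts gave the dimmest signal. The measure was thus chosen from the values, and the true background may differ. The number of arrays limits the precision of all results.

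Probe sets were named through GEO's platform annotation, with symbols updated through Entrez IDs from a RefSeq gene table of the assembly GRCm38.p6, which was used for names alone. Of 45101 probe sets, 64 were array controls, 34945 had 1 gene, 932 had several genes and 9160 had no listed gene. Of 18193 genes, 18032 had their symbol from the RefSeq table and 161 kept the symbol of the annotation. A gene with several probe sets was represented by the probe set with the highest mean. Of 2587 called genes with several probe sets, 1612 had another probe set called the same way and 33 had a probe set called the opposite way.

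Tests were run on log2(intensity + 16) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, knockout against control, no block, all genes, Benjamini-Hochberg adjustment). Fold changes on this scale understate the change of dim genes. Standard errors (SE) are those of the moderated fit, which shared its estimate of spread across genes and had 7.05 degrees of freedom. A gene was called at an adjusted p under 0.05. Gene lists of cell types, complexes and pathways were written before the data were examined. They were matched by current or listed older symbols, so that 988 of 1105 listed genes were measured, and 45 lists had at least 5 measured genes. Of 69 listed cytosolic ribosomal protein genes 39 were measured. Probe sets that match several genes were not used, which may have left out some of the others. Lists were tested with camera, a test of whether the genes of a list rank apart from all others, with its preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 45 lists. The estimated correlation of camera and fry, a rotation test of the list itself, were run beside it. Of the lists, lgr5_stem_cell and wnt_targets shared 8 genes, apoptosis and p53_targets 5, and other pairs 3 or fewer.

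The rule for named genes was also fixed before the data were examined. Yy1 came first. In each direction the 12 genes with the largest log2 change followed, among called genes with both knockout arrays on the same side of both controls and the higher group's mean above the median of all probe sets. Gene models without a standard name were skipped. From each list up to 4 members with the smallest unadjusted p were taken, and those of them that were not called are not named in the report, except Col1a2. Lgr5, Ascl2, Olfm4, Lyz1, Muc2, Chga, Dclk1, Alpi, Mki67, Cdkn1a, Tfam, Zfp42 and Yy2 were always given, and Yy2 had no probe set of its own among those used. Where 5 or fewer members of a list were called in a direction, all were named, and those beyond the rule were chosen after their values were seen.

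The fit was tested on simulated data with the real means of 18193 genes, in 10 draws with 200 changed genes each. With error variances drawn from the fitted prior, 23.4% of genes changed 1.5-fold, 89.1% of those changed 2-fold and 99.55% of those changed 4-fold were recovered, and 6.00% of calls were false. With each gene's own moderated variance, recovery was 82.5%, 99.7% and 100% and 8.73% of calls were false. The 200 changed genes are a smaller share than the 24.4% called in the real data, and errors were drawn independently for each gene. The shares recovered and false may therefore differ in the reported fit. The list test found a simulated list of 25 genes shifted by 0.5 on the log2 scale and called 5 of 200 unshifted lists at an unadjusted p under 0.05.

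The alternatives fixed beforehand were quantile normalization, median centring, pseudocounts of 1 and 64, filters on dim genes, the mean or the dimmest of a gene's probe sets, a trended and robust prior, array weights, the replicate number as a block, leaving out each array in turn, an adjusted p under 0.10, a test without moderation and camera on ranks. A fit without probe sets marked by the manufacturer as matching several transcripts, and a test of gene families that share the start of their symbol, were added after the data were seen. RNA quality was compared through the array's 3' and 5' control probe sets of Gapdh and Actb, with exact permutation tests, for which 2 arrays against 2 allow no two-sided p under 0.333. Probe sets without a single gene were tested as a class and counted.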

Results

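Transcript levels of jejunal crypt epithelium were compared between 2 arrays of Yy1 knockout mice and 2 arrays of control mice, to ask which transcripts differ in crypts after the loss of YY1, a zinc finger transcription factor that binds many promoters. Whether the control mice carried Cre-ERT2 or received tamoxifen was not clear from the labels. Effects of either could therefore not be told apart from the loss of Yy1. Values are intensities. Group means are given ± SD and log2 differences, knockout minus control on log2(intensity + 16), ± SE, each with n = 2 arrays per group. Calls were made at an adjusted p under 0.05. Across genes, which are not independent replicates, the 2 control arrays correlated at r = 0.996 and the 2 knockout arrays at r = 0.993, and pairs of 1 control and 1 knockout array between 0.963 and 0.976.

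Yy1 itself was lower in both knockout arrays with each of its 4 probe sets. The brightest probe set fell from 1664 ± 23.4 to 68.7 ± 0.940 (log2 difference -4.31 ± 0.10). The next one, used as the value of the gene, went from 1029 ± 31.8 to 141 ± 1.59 (-2.74 ± 0.10). The remaining probe sets went from 584 ± 23.3 to 57.4 ± 3.40 (-3.03 ± 0.10) and from 188 ± 18.3 to 63.1 ± 2.64 (-1.37 ± 0.11). The adjusted p over all probe sets, by limma, lay between 1.56e-05 and 0.000780. Where these probe sets lie relative to the deleted part of the gene was not analysed here. The median of the Bacillus control probe sets, 31.9 to 35.6, marks the background of these levels.

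**Figure D1:**
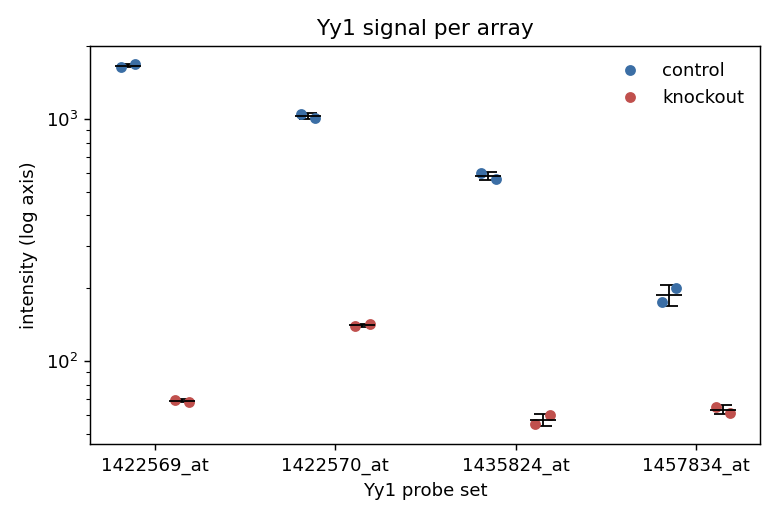
Intensity of the 4 Yy1 probe sets in each array, on a log axis. Points are arrays (control blue, knockout red), and black marks show the group mean ± SD with n = 2. With each probe set both knockout arrays lie below both control arrays, for the brightest probe set at 69.4 and 68.1 against 1648 and 1681.

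Knockout and control crypts differed in a large part of the measured genes. Of 18193 genes, 2445 were higher and 1994 lower in the knockout, 24.4% in all. Among these, 1250 were at least 1.5-fold higher and 1133 at least 1.5-fold lower, and 236 rose and 469 fell at least 2-fold. The 2 groups did not overlap in 62.0% of genes, where chance gives 33.3%. The number of calls rests on sharing the spread across genes: without moderation 2 genes were higher and 0 lower, and at an unadjusted p under 0.05 limma counted 6445. With 1 array left out, limma counted 1326 higher and 1040 lower genes without control replicate 1, 1157 and 1066 without control replicate 2, 1481 and 1289 without knockout replicate 1, and 2307 and 2059 without knockout replicate 2.

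Among the genes with the largest falls, Cyp3a25, a cytochrome P450, fell from 1417 ± 195 to 70.4 ± 23.1 (log2 -4.07 ± 0.19, 16.8-fold). Cubn, the cubilin receptor for vitamin B12 bound to intrinsic factor, fell from 1954 ± 342 to 104 ± 29.1 (-4.05 ± 0.19). Plb1, a brush border phospholipase, fell from 2293 ± 103 to 127 ± 27.2 (-4.03 ± 0.14). Slc5a4b and Slc5a4a, related members of the sodium/glucose cotransporter family whose probe sets may share targets, also fell. For Slc5a4a the log2 difference was -3.87 ± 0.24, while Slc5a4b went from 750 ± 247 to 35.8 ± 12.6, a knockout level at background that leaves the size of its fall open. The other genes among the 12 largest falls were Npl (-3.71 ± 0.19), which breaks down sialic acid, Maob (-3.66 ± 0.22), a monoamine oxidase, and the enterocyte gene Tmigd1 (-3.64 ± 0.18). They also held the phosphate transporter Slc34a2, from 476 to a knockout level of 28.8 at background, which leaves the size of its fall open, the nuclease Dnase1 (-3.45 ± 0.17), Fam151a (-3.32 ± 0.28) and the retinol dehydrogenase Rdh7 (-3.27 ± 0.23). For these 12 genes the adjusted p by limma was between 0.000101 and 0.000770.

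Esr1, the gene of estrogen receptor alpha, rose from 17.3 ± 3.14 to 291 ± 89.7. Its control level lay under the Bacillus medians, so the log2 difference of 3.17 and its place as the largest rise are not exact. It was seen with 1 of its 3 probe sets, while the other 2 gave 0.12 ± 0.12 and 0.15 ± 0.11 at levels between 44.8 and 57.9. The Cre-ERT2 transgene of the knockout mice carries part of an estrogen receptor, so the signal may come from the transgene or from the mouse gene. Btbd19 rose from 155 ± 36.2 to 727 ± 216 (2.10 ± 0.22), Rgcc, a regulator of the cell cycle, by 2.07 ± 0.17, and the long noncoding RNA Pvt1 by 2.07 ± 0.24. Ephx1, an epoxide hydrolase, rose by 1.98 ± 0.12, and the p53 targets Psrc1 and Eda2r by 1.93 ± 0.11 and 1.90 ± 0.29. The remaining genes were Mns1 (1.87 ± 0.14), Nlrc5 (1.78 ± 0.14), an activator of MHC class I genes, the serine synthesis enzyme Psat1 (1.77 ± 0.16), Noxred1 (1.71 ± 0.09) and Rad18 (1.71 ± 0.13), a ubiquitin ligase of DNA damage tolerance. Their adjusted p by limma was between 0.000225 and 0.00438.

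**Figure D2:**
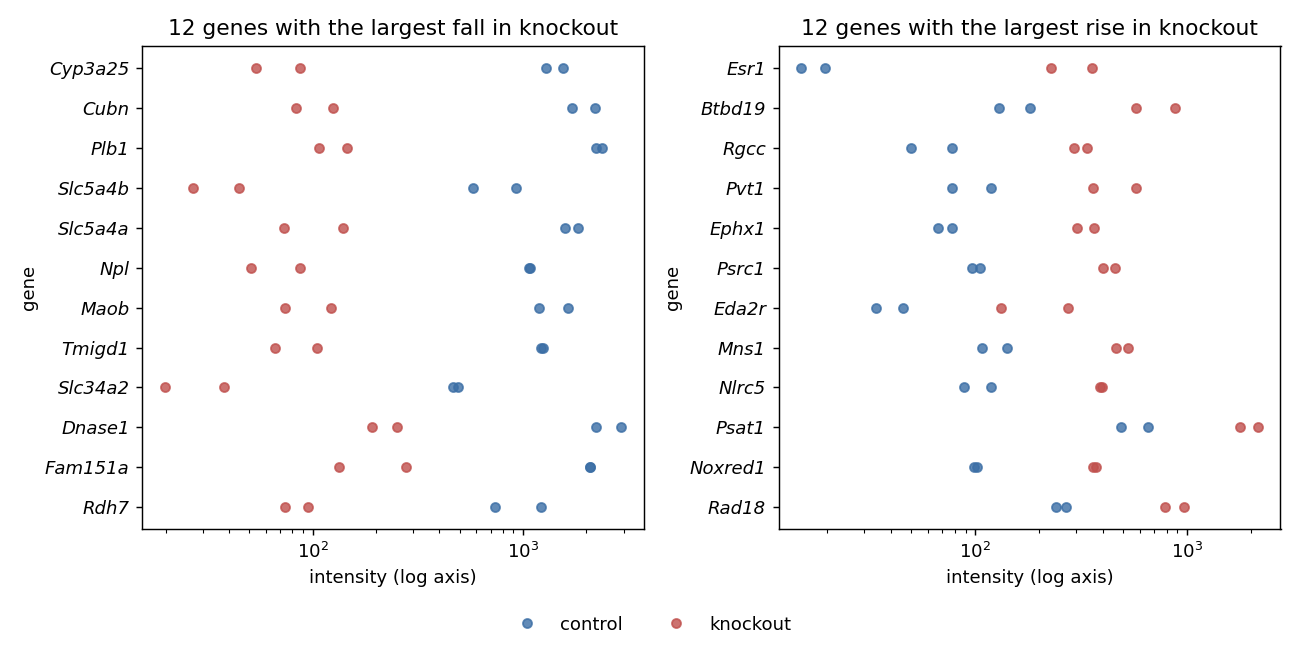
Intensity of the 12 genes with the largest fall and the 12 with the largest rise, on a log axis. Each point is 1 array (control blue, knockout red). By the rule that chose these genes, the 2 knockout arrays lie apart from the 2 control arrays in each, for Plb1 at 108 and 146 against 2366 and 2220.

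Of the 45 gene lists, camera placed 10 higher and 12 lower in the knockout. With the correlation between genes estimated from these 4 arrays no list passed the threshold, and the lowest adjusted p was 0.637. The directional test of fry passed 0 lists, with 0.063 as its lowest adjusted p, and its mixed test passed 41. List statements below therefore rest on the preset correlation, and the counts of called members stand beside them. These counts are to be read against the 2445 higher and 1994 lower of all 18193 genes. For some lists that camera placed lower, the share of falling members was near that of all genes. Examples are complex V, with 2 of 18, and mesenchyme, with 2 of 20, where the counts add no evidence. RNA quality differed between the groups: the 3' minus 5' log2 difference of the Gapdh control probe sets was 1.67 ± 0.0426 (SD) in knockout and 1.41 ± 0.0314 in control arrays. The Actb values were 0.31 ± 0.0260 and 0.26 ± 0.0255. In both, the knockout arrays were higher, and the exact permutation p was 0.333, the smallest that 2 arrays against 2 can give. This difference goes along with all the list differences that follow. The share of enterocytes and of dividing cells in each preparation was not measured. For these lists, a difference in cell share therefore cannot be told apart from a change within cells.

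Enterocyte markers, the genes of the mature absorptive cell, were lower as a list. Of 36 measured, 28 fell and none rose, and 35 fell when adjusted over the list alone (median log2 -0.87, camera adjusted p = 1.12e-15, adjusted p = 0.659 with an estimated correlation). After Tmigd1, the members with the smallest p were the peptidases Xpnpep2 (-2.38 ± 0.14) and Mep1a (-2.62 ± 0.19) and the glucose transporter Slc2a2 (-2.32 ± 0.23). Alpi, the intestinal alkaline phosphatase, fell from 3678 ± 150 to 1209 ± 617 (-1.69 ± 0.30). The knockout arrays differed in degree: the mean of the list was lower than in controls by 1.59 in knockout replicate 1 and by 0.89 in knockout replicate 2. Intestinal transcription factors were lower as a list, with 6 of 22 falling and 2 rising, or 9 falling and 2 rising when adjusted over the list alone (camera adjusted p = 0.0136, adjusted p = 0.637 with an estimated correlation). Gata5 (-1.01 ± 0.11), Gata6 (-0.58 ± 0.10) and Hnf4g (-0.79 ± 0.18) fell, and Onecut2 (0.61 ± 0.12) and Foxa1 (0.34 ± 0.10) rose.

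Of 25 goblet cell genes 6 fell, among them St3gal6 (-0.98 ± 0.13), Clca1 (-0.47 ± 0.11) and Ccl6 (-0.41 ± 0.10), and S100a6 rose (0.72 ± 0.11), with the same counts when adjusted over the list alone. The goblet list was lower with camera adjusted p = 0.0126, adjusted p = 0.750 with an estimated correlation and 0.0556 by camera without knockout replicate 1. Muc2, the main mucin, had 3941 ± 318 in control and 3282 ± 327 in knockout (-0.26 ± 0.12, adjusted p = 0.156). Of 22 tuft cell genes 5 fell, or 6 when adjusted over the list alone: Alox5ap (-0.82 ± 0.10), Rgs13 (-0.69 ± 0.12), Dclk1 (-0.57 ± 0.11), Ptpn6 (-0.43 ± 0.10) and the tuft cell regulator Pou2f3 (-0.45 ± 0.11). The tuft list had camera adjusted p = 0.00284, and adjusted p = 0.665 with an estimated correlation. Of 27 enteroendocrine genes, the hormone genes Ghrl (0.46 ± 0.10) and Cck (0.41 ± 0.10) rose, and Isl1 (-0.55 ± 0.11), Nts (-0.78 ± 0.17) and Sct (-0.56 ± 0.13) fell, with the same counts when adjusted over the list alone. The enteroendocrine list did not pass (camera adjusted p = 0.701), and Chga stood at 642 ± 82.3 and 630 ± 17.7. Of 13 Paneth cell genes Mmp7 (0.42 ± 0.10) and Defa3 (0.56 ± 0.16), one of a family of near-identical defensins, rose, and Guca2b (-0.85 ± 0.22), whose product is also made by other epithelial cells, fell. These counts were also 2 and 1 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.865; median log2 -0.01, mean 0.03). Lyz1, the Paneth lysozyme, was at 11876 ± 290 in control and 11150 ± 549 in knockout (-0.09 ± 0.10, adjusted p = 0.571).

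Lgr5 stem cell markers did not move as a list (camera adjusted p = 0.281). Of 24 measured, Vdr (-1.23 ± 0.14), Nrn1 (366 ± 78.6 to 174 ± 22.7), Olfm4 (-0.62 ± 0.10) and Fstl1 (-0.44 ± 0.12) fell and Cdk6 (0.67 ± 0.15) and Scn2b (0.53 ± 0.13; -0.45 with its dimmest probe set) rose, with the same counts when adjusted over the list alone. Lgr5 itself was dim, at 67.7 ± 2.04 and 61.4 ± 2.57 (adjusted p = 0.460). Ascl2, a transcription factor of the stem cell, was at 129 and 125 (log2 -0.04 ± 0.11, adjusted p = 0.835). Of 22 Wnt target genes Cd44 (0.96 ± 0.13), Tiam1 (0.71 ± 0.16) and Mmp7 rose and Prox1 (-0.48 ± 0.13) fell, or 3 rose and none fell when adjusted over the list alone. The Wnt list did not pass (camera adjusted p = 0.967; median log2 -0.03, mean 0.04). Of 20 genes of reserve stem cells and regeneration, Tert (0.65 ± 0.17) and Ankrd1 (0.35 ± 0.10) rose and Bmi1 (-0.50 ± 0.13) fell, 0 of them when adjusted over the list alone (camera adjusted p = 0.667). Zfp42, an early-embryo gene related to Yy1, was near background at 35.3 ± 2.32 and 35.5 ± 2.70 (adjusted p = 0.975).

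Cell cycle genes were higher as a list. Of 37 measured, 25 rose and Foxm1 fell, and 29 rose when adjusted over the list alone (median log2 0.70, camera adjusted p = 6.63e-12, adjusted p = 0.637 with an estimated correlation). Bub1 of the spindle checkpoint rose by 1.36 ± 0.13, the kinase Cdk1 by 0.97 ± 0.10, the replication helicase subunit Mcm4 by 1.10 ± 0.11 and the kinetochore gene Cenpf by 0.91 ± 0.10. Mki67 was at 4779 ± 188 and 5908 ± 124 (0.31 ± 0.10, adjusted p = 0.0597). The fall of Foxm1 rests on 1 probe set (-0.64 ± 0.12), while another of its 4 probe sets rose by 0.91 ± 0.10.

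Genes for building cytosolic and mitochondrial ribosomes were higher. Of 28 ribosome biogenesis genes 23 rose, or 26 when adjusted over the list alone, and none fell (median log2 0.75, camera adjusted p = 6.63e-12, adjusted p = 0.637 with an estimated correlation). Utp20 (1.46 ± 0.12), Nop14 (1.05 ± 0.10), Fbl (0.96 ± 0.10), the rRNA methyltransferase, and the helicase Ddx21 (0.98 ± 0.11) led. Of 76 mitochondrial ribosomal protein genes 41 rose and 3 fell, or 46 and 3 when adjusted over the list alone (median log2 0.41, camera adjusted p = 9.19e-10, adjusted p = 0.637 with an estimated correlation). Mrps11 (1.02 ± 0.09), Mrpl3 (0.94 ± 0.10), Mrps14 (0.83 ± 0.09) and Mrpl13 (0.87 ± 0.10) rose, and Mrpl23 (-0.84 ± 0.10), Mrpl27 (-0.68 ± 0.09) and Mrpl42 (-0.42 ± 0.10) fell. Of 39 measured cytosolic ribosomal protein genes 7 rose, or 5 when adjusted over the list alone (camera adjusted p = 0.000626, adjusted p = 0.637 with an estimated correlation). They included Rps25 (1.58 ± 0.15), Rpl14 (1.13 ± 0.13), Rpl12 (1.03 ± 0.16) and Rps6 (0.59 ± 0.11; -0.050 with its dimmest probe set).

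The respiratory chain moved downward in part. Of 34 complex I genes 6 fell and Ndufs5 rose (0.35 ± 0.10), with the same counts when adjusted over the list alone. The falls with the smallest p were Ndufc1 from 5890 ± 25.1 to 2641 ± 2.35 (-1.15 ± 0.09), Ndufb11 (-0.71 ± 0.09), Ndufa3 (-0.63 ± 0.10) and Ndufs7 (-0.58 ± 0.10). As a list complex I missed the threshold (median log2 -0.05, camera adjusted p = 0.0514), and passed it at 0.0377 with a pseudocount of 64, at 0.0187 with a trended and robust prior and at 0.0415 without control replicate 2. Of 14 genes of complexes II and III, Uqcrc1 (-0.77 ± 0.11), Sdhc (-0.69 ± 0.10) and Sdha (-0.41 ± 0.10) fell (camera adjusted p = 0.0219, adjusted p = 0.686 with an estimated correlation). Of 18 complex V genes, Atp5g2 (-0.49 ± 0.09) and Atp5o (-0.48 ± 0.11) fell (camera adjusted p = 0.0170, adjusted p = 0.750 with an estimated correlation). Counts adjusted over the list alone were the same, 3 and 2. Without knockout replicate 1 both lists missed the threshold, at 0.0520 and 0.0679, and complexes II and III also without control replicate 1, at 0.0528, and with the dimmest probe set of each gene, at 0.0540. Of 20 complex IV genes Cox7a1 (-2.02 ± 0.19) and Cox8a (-0.50 ± 0.12) fell and the assembly genes Cox18 (1.19 ± 0.11) and Cox15 (0.40 ± 0.10; -0.25 with its dimmest probe set) rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.552).

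Genes of fatty acid oxidation, the tricarboxylic acid cycle and oxidative stress were lower as lists, while mitochondrial biogenesis genes were higher. Of 24 fatty acid oxidation genes 15 fell, or 17 when adjusted over the list alone, and none rose (median log2 -0.47, camera adjusted p = 1.26e-07, adjusted p = 0.637 with an estimated correlation). Eci1 fell from 2088 ± 79.4 to 494 ± 1.20 (-2.04 ± 0.10), and Echs1 (-1.41 ± 0.12), Acaa1b (-2.58 ± 0.23) and Acot2 (-1.30 ± 0.13) also fell. Of 20 genes of the tricarboxylic acid cycle 8 fell, or 11 when adjusted over the list alone, led by Suclg2 (-1.18 ± 0.12), Ogdh (-0.68 ± 0.14), Idh2 (-0.46 ± 0.10) and Pdhx (-0.57 ± 0.13). That list had camera adjusted p = 0.000658, and adjusted p = 0.637 with an estimated correlation. Of 25 mitochondrial biogenesis genes 10 rose, or 12 when adjusted over the list alone, among them the import genes Tomm20 (0.58 ± 0.11) and Tomm40 (0.66 ± 0.12) and the mitochondrial DNA factor Tfam (0.56 ± 0.11). In this list Ppargc1a, the coactivator PGC-1alpha, fell from 1843 ± 63.0 to 534 ± 159 (-1.79 ± 0.19), and 3 genes were lower when adjusted over the list alone. The biogenesis list had camera adjusted p = 0.0136, and adjusted p = 0.750 with an estimated correlation. It missed the threshold without control replicate 2 (0.0970), without knockout replicate 1 (0.0556) and with the dimmest probe set of each gene (0.0540). Of 22 oxidative stress genes 8 fell and 2 rose, or 12 and 4 when adjusted over the list alone. Those falling included catalase Cat (-1.45 ± 0.13), Prdx3 (-1.05 ± 0.11), Gstm1 (-1.74 ± 0.18) and Gstm3 (-2.56 ± 0.28), while the metallothioneins Mt1 (0.75 ± 0.19) and Mt2 (1.23 ± 0.32) rose (camera adjusted p = 0.00954, adjusted p = 0.637 with an estimated correlation).

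Stress pathways were higher in part. Of 27 p53 target genes 15 rose, and Sesn1 (-1.12 ± 0.25) and Btg2 (-0.65 ± 0.15) fell, or 15 and 4 when adjusted over the list alone (median log2 0.41, camera adjusted p = 0.00115, adjusted p = 0.637 with an estimated correlation). Besides Psrc1, they included Ccng1 (1.33 ± 0.10), Zmat3 (1.03 ± 0.10) and the nuclease Aen (1.34 ± 0.15). Cdkn1a, the p21 cell cycle inhibitor, was at 3429 ± 169 and 2943 ± 615 (-0.23 ± 0.15, adjusted p = 0.324). Of 31 genes of the integrated stress response 14 rose and 4 fell, or 16 and 5 when adjusted over the list alone (camera adjusted p = 0.00140, adjusted p = 0.637 with an estimated correlation). The rising genes Asns (1.43 ± 0.10), Shmt2 (1.28 ± 0.11) and Psat1 serve amino acid and one-carbon synthesis, and Cars (1.13 ± 0.09) is a tRNA synthetase. Vegfa (-0.82 ± 0.11), Slc3a2 (-0.78 ± 0.14), Vldlr (-0.42 ± 0.10) and Aldh1l2 (-0.37 ± 0.11) fell, but Vldlr was at 0.25 without probe sets matching several transcripts, a fit chosen after the data were seen. Of 23 genes of the unfolded protein response none was called, also when adjusted over the list alone (camera adjusted p = 0.667).

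**Figure D3:**
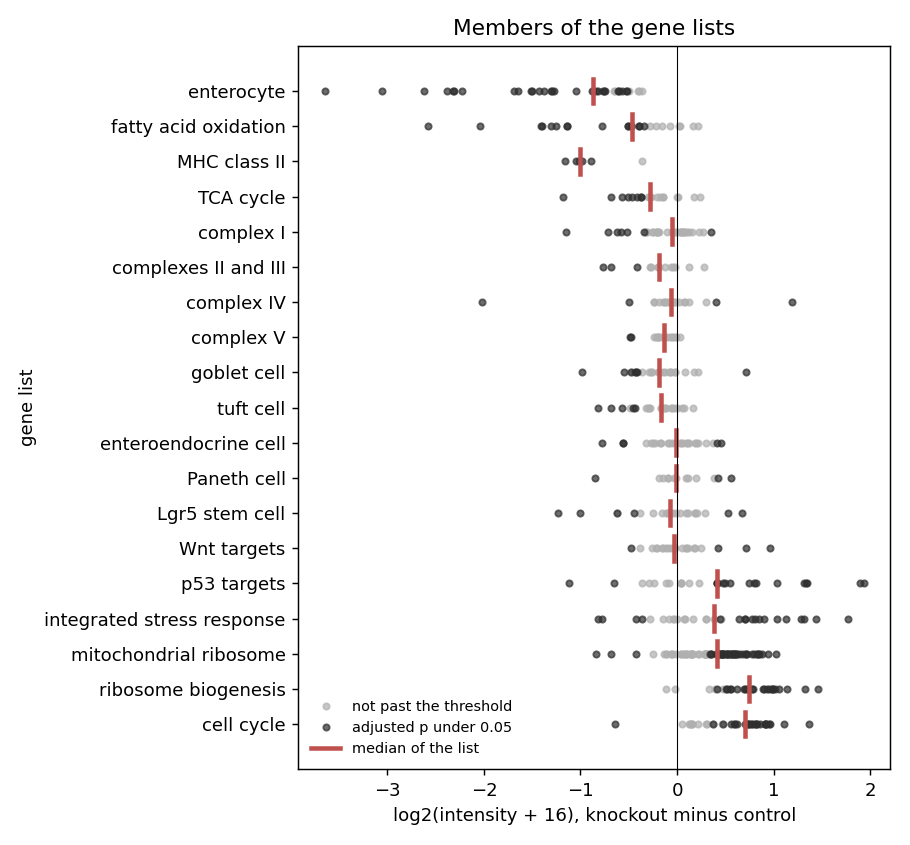
Log2 difference, knockout minus control, of each measured member of 19 gene lists. Dark points are called members, grey points are members not past the threshold, and the red bar is the median of the list, at -0.87 for enterocyte and 0.70 for cell cycle genes.

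Further lists fixed beforehand also passed camera. Of 6 MHC class II genes 5 fell, or 6 when adjusted over the list alone: H2-Eb1 (-1.16 ± 0.10), H2-DMa (-0.99 ± 0.12), Cd74 (-1.05 ± 0.15), H2-Ab1 (-0.89 ± 0.16) and H2-Aa (-1.02 ± 0.21), with camera adjusted p = 0.000141 and adjusted p = 0.637 with an estimated correlation. Of 17 epithelial antimicrobial genes Reg3a (-2.36 ± 0.20), Duoxa2 (-1.50 ± 0.24) and Pigr (-0.40 ± 0.10) fell, also when adjusted over the list alone (camera adjusted p = 0.0190, adjusted p = 0.686 with an estimated correlation, and 0.0852 by camera without control replicate 2). Of 14 genes of INO80, a chromatin remodelling complex known to bind YY1, 8 rose, or 9 when adjusted over the list alone, led by Ruvbl1 (1.43 ± 0.13), Ino80 (1.26 ± 0.14), Nfrkb (0.66 ± 0.10) and Actl6a (0.57 ± 0.10) (camera adjusted p = 0.00115, adjusted p = 0.637 with an estimated correlation). Of 30 interferon response genes 8 rose, also when adjusted over the list alone, including Xaf1 (1.28 ± 0.14), Irgm1 (0.65 ± 0.11), Gbp3 (0.57 ± 0.10) and Oas1a (0.87 ± 0.16), and Ifi27l2a fell (-0.53 ± 0.11) (camera adjusted p = 0.00954, adjusted p = 0.825 with an estimated correlation). The interferon list missed the threshold without control replicate 1 (0.0528), without knockout replicate 2 (0.371) and without genes under the median (0.108). Of 18 cholesterol synthesis genes 6 rose, or 7 when adjusted over the list alone, with Fdps (0.70 ± 0.11; -0.0041 with its dimmest probe set), Pmvk (0.71 ± 0.11), Hsd17b7 (0.61 ± 0.11) and Cyp51 (0.47 ± 0.10) in front (camera adjusted p = 0.00750, adjusted p = 0.637 with an estimated correlation, and 0.0540 by camera with the dimmest probe set of each gene).

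Some lists that did not pass camera held called members. Of 29 polycomb genes 7 rose, among them Eed (0.96 ± 0.10; -0.020 with its dimmest probe set) and Ezh2 (0.66 ± 0.10), and Pcgf2 (-0.74 ± 0.10; 0.079 with its dimmest), Phc3 (-0.65 ± 0.11), Cbx6 (-0.55 ± 0.14) and Bmi1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.608). Of 32 Hox genes Hoxa5 (-0.54 ± 0.11) and Hoxb3 (-0.35 ± 0.10) fell, and 0 when adjusted over the list alone (0.667), but with the dimmest probe set of each gene Hoxa5 was at 0.067 and Hoxb3 at 0.081. In the Notch pathway, Jag1 (0.92 ± 0.10) and Notch2 (0.58 ± 0.13) rose and Olfm4, Maml1 (-0.50 ± 0.10), Lfng (-0.39 ± 0.10) and Dll1 (-0.46 ± 0.13) fell (with their dimmest probe sets Maml1 was at 0.028 and Lfng at 0.065; 19 genes, 2 higher and 6 lower when adjusted over the list alone, 0.213). In glycolysis, Pdk1 rose (0.49 ± 0.11) and Tpi1 (-0.61 ± 0.09), Slc16a3 (-0.57 ± 0.12), Aldoc (-0.70 ± 0.15) and Pkm (-0.47 ± 0.11) fell (17 genes, the same counts when adjusted over the list alone, 0.251). Of the junction genes, Cldn2 (0.64 ± 0.12) and Pkp2 (0.43 ± 0.10) rose and Cldn4 (-0.75 ± 0.11), Cldn15 (-0.64 ± 0.13) and Tjp3 (-0.34 ± 0.10) fell (23 genes, 2 higher and 2 lower when adjusted over the list alone, 0.258, and 0.0406 with the dimmest probe set of each gene). Of 19 iron and heme genes 6 fell, among them Slc25a37 (-0.79 ± 0.11), Alas1 (-0.49 ± 0.09), Heph (-0.77 ± 0.15) and Aco1 (-0.54 ± 0.11), and Nfs1 (0.60 ± 0.13), Uros (0.66 ± 0.14, but -0.25 with its dimmest probe set) and Iscu (0.39 ± 0.10) rose, or 7 and 3 when adjusted over the list alone (0.0795). The iron and heme list passed as lower with the mean (0.0296) or the dimmest (0.0310) of the probe sets of each gene and without knockout replicate 1 (0.0378). Of 23 apoptosis genes Tnfrsf10b (0.75 ± 0.12) and Aifm1 (0.33 ± 0.10) rose and Casp9 (-0.66 ± 0.09), Bcl2l1 (-0.45 ± 0.10) and Bad (-0.36 ± 0.10) fell, or 3 and 3 when adjusted over the list alone (0.701; median log2 -0.03, mean 0.00109).

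Markers of cells outside the epithelium showed few calls. The mesenchyme list was lower with camera adjusted p = 0.0437 and adjusted p = 0.637 with an estimated correlation. Of its 20 genes Fbln1 fell from 2183 ± 108 to 703 ± 128 (-1.62 ± 0.14) and Pdgfra from 104 to 48.4 (-0.90 ± 0.10; 0.046 with its dimmest probe set), also when adjusted over the list alone. The list missed the threshold without control replicate 2 (0.223), without knockout replicate 2 (0.253), with a pseudocount of 64 (0.0577) and without genes under the 25th percentile (0.0833) or the median (0.134). It also missed it with the mean (0.193) or the dimmest (0.529) of the probe sets of each gene. Of 21 T and NK cell genes Cd3g (-0.69 ± 0.11) and Zap70 (-0.67 ± 0.16, but 0.18 with its dimmest probe set) fell (camera adjusted p = 0.667), and of 20 myeloid genes Cd14 rose (1.15 ± 0.10; 0.667). Of 13 smooth muscle genes Tagln rose (0.41 ± 0.11) and Mylk (-0.49 ± 0.10), Smtn (-0.37 ± 0.10) and Des (-0.81 ± 0.24, but 0.093 with its dimmest probe set) fell (0.701). Of 14 endothelial genes Prox1 fell (0.843; median log2 -0.02, mean 0.01), and of 6 erythroid genes Hba-a2 fell (-0.73 ± 0.10; 0.667). None of 14 B and plasma cell genes (0.552), 10 genes of enteric neurons and glia (0.553) and 8 exocrine pancreas genes (0.552) was called.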

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

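All tests in this part were chosen only after the results were seen. Bootstrap intervals came from 10000 draws that resampled the genes of a list, not the arrays. Genes of a list are not independent replicates, so these intervals do not measure the spread between mice.

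Probe sets without a single named gene also differed between knockout and control crypts. Of 10092 such probe sets, 609 were higher and 607 lower in the knockout at an adjusted p under 0.05, together 12.05%, against 22.3% of the probe sets with 1 gene. They drew attention as signal that the gene-level results leave out. Which transcripts they report on was not analysed here.

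The rise of Esr1 in the knockout arrays rested on 1 probe set, at 3.17 on the log2 scale, while the highest of the other Esr1 probe sets was 0.15. The control level of that probe set, 17.3, lay under the Bacillus medians, so the size of the rise is not exact. A transcript of the Cre-ERT2 transgene, which carries part of an estrogen receptor, would give signal with the probe sets inside that part alone, and the values are of that kind. More transcript of the mouse gene would be expected with the other probe sets too, but these lay at 1.52 times the median of the bacterial control probe sets or above, so near background that a rise could have been missed. Where the probe sets lie in the gene was not analysed here, so both explanations stay open.

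Enterocyte genes were lower and cell cycle genes higher in the same arrays, which a smaller share of enterocytes in the crypt preparation could give. If it did, markers of other epithelial types would be expected to rise along with the cell cycle genes. Stem, Paneth, goblet, enteroendocrine and tuft markers above the median level of all probe sets had a median of -0.10. The cell cycle median lay 0.80 above it (95% bootstrap interval 0.56 to 0.92), so these markers did not rise together with it. The comparison cannot exclude the explanation for the rise, since some of these markers were called lower and dividing cells had no separate list. For the fall of the enterocyte genes it stays open too: 0 of the markers past the test rose, and the log2 differences had an SD of 0.82, which dilution by 1 factor would make smaller. A scaling factor per array moves all genes the same way and was excluded as the cause of the opposite directions, since the list medians lay 1.57 apart (95% bootstrap interval 1.294 to 2.095) on either side of 0, while a larger share of dividing cells stays open.

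The fall of the enterocyte genes was smaller in knockout replicate 2, by 0.89 against 1.59 in knockout replicate 1. Cells that kept Yy1 in replicate 2 would bring back Yy1 as well. The Yy1 probe sets lay at most 0.910% of the way back to control, against 36.0% for the median enterocyte gene (95% bootstrap interval 29.1 to 45.5). For these 2 arrays the values argue against such cells as the cause, if they were spread evenly over the cell types of the preparation. Had mainly enterocytes kept Yy1, its return could be smaller than theirs, which was not tested. Over all genes knockout replicate 2 lay nearer to the controls, at r = 0.975 and 0.976, against 0.964 and 0.963 for knockout replicate 1. Replicate 2 thus differed less on the whole array, but whether this accounts for the enterocyte genes stays open. The ratio of replicate 2 to replicate 1 was 0.563 for the enterocyte genes (95% bootstrap interval 0.490 to 0.628). It was between 0.738 and 0.829 for ribosome biogenesis, fatty acid oxidation, mitochondrial ribosome and cell cycle genes, each with an interval under 1. For the tricarboxylic acid cycle it was 0.843 (0.638 to 1.04), for p53 targets 1.18 (0.910 to 2.83) and for the integrated stress response 1.20 (0.951 to 2.11). A later stage of the loss in replicate 1, or a different share of villus cells, was not tested.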

How the results depend on the processing

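The fit without probe sets matching several transcripts was chosen only after the result was seen. Of 206 genes followed across the settings, 191 passed the test in the reported fit. Of these, 168 kept call and direction under all settings that kept the arrays, the probe sets and moderation. A gene left out by a filter on dim genes was judged on the other settings alone. Of the 191, 16 turned direction in some setting. The number of calls depended on the number of arrays and on shared spread. Of the 4439 reported calls, 4281 were also made after quantile normalization, 4356 after median centring and 4406 with array weights, and none turned direction. With the mean of probe sets 3815 were kept and 1 turned, and with the dimmest probe set 2746 were kept and 20 turned. Without control replicate 1 or 2, 2299 and 2166 were kept, and without knockout replicate 1 or 2, 2659 and 3741. Over all genes, a pseudocount of 1 left 3904 calls. Where a list or gene below moved, the cause was not tested, except that fits with 1 array left out have fewer samples.

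Without moderation 2 genes were higher and 0 lower. With 1 array left out, between 1157 and 2307 genes were higher and between 1040 and 2059 lower. With the replicate number as a block, which pairs arrays that share only a number, 2662 genes were higher and 2219 lower, and the Wnt list turned direction at 0.927 without passing; the deviations of replicate 1 in the 2 groups correlated at r = 0.097.

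With the estimated correlation of camera, 0 lists were higher and 0 lower, with adjusted p of 0.637 for cell cycle, mitochondrial ribosome, p53 targets and tricarboxylic acid cycle, 0.659 for enterocyte, 0.665 for tuft, 0.686 for complexes II and III and 0.750 for goblet and complex V. By fry 0 and 0 passed, with 0.063 for the first 4 of these, 0.132 for enterocyte, 0.109 for tuft, 0.0712 for complexes II and III, 0.238 for goblet and 0.135 for complex V. With 1 array left out, the adjusted p of camera ranged from 0.00494 to 0.0556 for goblet, 0.0352 to 0.0528 for complexes II and III, 0.0180 to 0.0679 for complex V and 0.0415 to 0.122 for complex I. Complex I passed at 0.0377 with a pseudocount of 64 and at 0.0187 with a trended and robust prior, and complexes II and III had 0.0540 with the dimmest probe set.

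Lists that never passed turned direction in some fits: with 1 array left out Wnt (0.867 to 0.968), Paneth (0.678 to 0.968), enteroendocrine (0.402 to 0.949), myeloid (0.250 to 0.952), unfolded protein response (0.190 to 0.949), apoptosis (0.602 to 0.981) and endothelium (0.848 to 0.943). Wnt also turned with a pseudocount of 1 (0.994), the mean of probe sets (0.824), the dimmest probe set (0.825) and ranks (0.886). Paneth (0.803) and reserve stem cell genes (0.965) turned without genes under the median, the unfolded protein response with the mean of probe sets (0.945) and the dimmest probe set (0.753), and B and plasma cells with the dimmest (0.597).

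The log2 difference of some genes turned with another choice of probe set. With the mean of probe sets Foxm1 was at 0.17 and Lyz1 at 0.019. With the dimmest probe set Fdps was at -0.0041, Rps6 at -0.050, Pdgfra at 0.046, Col1a2 at 0.12, Cox15 at -0.25, Eed at -0.020, Pcgf2 at 0.079, Foxm1 at 0.21, Hoxa5 at 0.067, Hoxb3 at 0.081, Uros at -0.25, Scn2b at -0.45, Maml1 at 0.028, Lfng at 0.065, Des at 0.093, Zap70 at 0.18 and Lyz1 at 0.25. Col1a2, of the mesenchyme list, was at -0.40 in the reported fit and was not called there. Without probe sets matching several transcripts, Hoxa5 was at 0.067, Vldlr at 0.25 and Lyz1 at 0.25. With 1 array left out Ascl2 ranged from -0.12 to 0.039, Chga from -0.15 to 0.11 and Zfp42 from -0.047 to 0.060.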

Other observations

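The gene families of this part were chosen only after the results were seen, as the 116 groups of at least 15 genes that share the start of their symbol.

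Some families of nuclear transport, transcription and RNA processing were higher in the knockout. Others of transcription did not pass, such as Taf (9 higher, 2 lower, camera adjusted p = 0.14) and Zfp (49 higher, 32 lower, 0.397). Of 19 nucleoporin genes (Nup) 15 were higher and 0 lower, with a median log2 difference of 0.62 (camera adjusted p = 3.13e-07, adjusted p = 0.922 with an estimated correlation, as for all families named here that passed). Of 25 RNA polymerase genes (Polr) 15 were higher and 0 lower (median 0.47, 7.80e-06), and of 17 tRNA methyltransferase genes (Trmt) 10 and 0 (0.58, 1.18e-05). Of 35 DEAD-box helicase genes (Ddx) 21 were higher and 1 lower (0.42, 3.44e-05), and of 16 Dhx helicase genes 10 and 1 (0.41, 0.00170). Of 47 translation factor genes (Eif) 17 were higher and 3 lower (0.25, 0.00319), of 22 general transcription factor genes (Gtf) 10 and 0 (0.32, 0.00729), and of 15 genes of import through the inner mitochondrial membrane (Timm) 7 and 0 (0.27, 0.00849). Among genes of DNA repair and of the centrosome, 9 of 16 Rad genes were higher and 0 lower (0.49, 0.00115), and 16 of 37 Cep genes higher and 2 lower (0.23, 0.00199).

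Some families of metabolism and transport were lower. Others did not pass, such as Slco (2 lower, 0 higher, camera adjusted p = 0.294) and Atp (6 lower, 5 higher, 0.379). Of 20 aldehyde dehydrogenase genes (Aldh) 9 were lower and 0 higher (median -0.21, camera adjusted p = 2.73e-05), and of 18 hydroxysteroid dehydrogenase genes (Hsd) 7 were lower and 2 higher (-0.34, 0.00351). Of 73 cytochrome P450 genes (Cyp) 20 were lower and 3 higher (-0.12, 0.00176), and of 347 solute carrier genes (Slc) 92 were lower and 27 higher (-0.07, 0.00179).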
